A study of Mus musculus with 2 samples.

How the data were processed

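Single-nucleus RNA sequencing was analysed from 2 libraries of cortical GABAergic nuclei, 1 from saline-injected and 1 from IL-13-injected mice. Per the labels' protocols, each library pooled sensory cortex of 1 male and 1 female mouse at postnatal day 15, taken 4 hours after a unilateral injection into the lateral ventricle, and 20000 sorted nuclei were loaded per library. The mice carried a Vgat-Cre driver with a nuclear-envelope GFP reporter (Sun1-sfGFP), and sorting kept single nuclei positive for Hoechst and GFP. Groups were taken from the treatment label of each library.

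The deposited values are UMI counts per gene and barcode, in filtered matrices of the 10x 3' v3.1 chemistry. Cell Ranger 7.0.1 and the mm10 genome are named in the submitters' processing notes. The annotation release, the handling of intronic reads and the use of strand were not given in the sources used here. The deposited matrices hold 32285 genes each, of which 78 share a symbol with another gene. Gene lengths and coordinates came from GENCODE M21 on GRCm38, matched by Ensembl identifier for 32158 of these genes.

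Nuclei with at least 500 detected genes and at most 5% mitochondrial UMIs were kept. This left 8716 of 8744 barcodes in the saline library and 7832 of 7926 in the IL-13 library. The mitochondrial limit was set after the values had been looked at, and 5 and 10 barcodes exceeded it, of which some also had too few genes. Doublets were called per library with the scrublet function of scanpy 1.11.5 at an expected rate of 7%, and the calls (4.13% of saline and 3.65% of IL-13 nuclei) were left out. Their median UMI counts were 12084 and 12356.5.

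Clustering used counts scaled to 10000 per nucleus and log-transformed, 3000 variable genes, 30 principal components (scikit-learn 1.9.0), 15 nearest neighbours with shared-neighbour weights and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Both libraries were clustered together without integration. Genes of 8 response lists, Xist, Tsix, Y-linked, mitochondrial and ribosomal protein genes were kept out, so that class sizes were not set by them. Cluster names came from marker lists fixed before the data were examined. A name needed at least 3 markers at 1.5 times the geometric mean of the clusters and 10 CPM, a mean log2 score above 0.25 for interneurons or at least 1.5 for other cells, and no other class with more markers among the 10 leading genes. These naming thresholds, and the minimum of 200 CPM of Gad1 and Gad2 for a GABAergic cluster, were set after the clusters had been seen. Clusters of low UMI content with no marker of a name among the leading genes stayed unnamed.

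UMIs were summed over all nuclei of GABAergic clusters per library and scaled to CPM by the sum of UMIs of these nuclei. The log2 ratio is IL-13 CPM over saline CPM. Its 95% interval is the exact conditional binomial interval of a ratio of counts, CPM have exact Poisson intervals, and shares have exact binomial (Clopper-Pearson) intervals. With 1 library per group there was no replicate, so no test between conditions was made and no p-value, standard error or number of changed genes is given. All intervals cover counting error only. Sums and intervals were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and anndata 0.12.19, and figures drawn with matplotlib 3.10.9.

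The main measures were medians of log2 ratios over 17 response lists fixed before the data were examined. A list member was measured with at least 30 UMIs over both libraries, which held for 18090 genes in all. Intervals of list medians came from 1000 Poisson resamplings of the counts. The percentile of each median among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries. A further percentile used random lists matched on 5 bins of gene length within 10 of expression and was added after the length trend had been seen. Marker lists of 22 cell types were measured in the same way.

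Nuclei were assigned to the female mouse with at least 3 Xist UMIs and no UMI of Uty, Ddx3y, Kdm5d or Eif2s3y, and to the male mouse with at least 1 UMI of those 4 genes and at most 1 of Xist. Sex and mouse cannot be separated within a pool, and these ratios were used only as a description and, by their sign, in the choice of named genes. Receptor detection was compared after thinning each nucleus to 2000 UMIs, leaving out shallower nuclei.

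Named genes followed a rule fixed before the data were examined. Over all GABAergic nuclei these were the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 10 CPM, at least 100 UMIs and the same sign in male and female nuclei. In each class with at least 300 nuclei per library they were the 3 highest and 3 lowest, and in each list up to 2 members at either end with at least 10 CPM, or of all measured members when fewer than 4 reached it. Il4ra, Il13ra1, Il13ra2, Il2rg, Stat6, Socs1, Socs3, Cish and class markers were always named. Sex-linked, mitochondrial and haemoglobin genes and gene models without a symbol of their own were kept out of the ranking. Other genes that the text names (Arc, Fos, Egr3, Nptx2 in the sum over all nuclei, Mt1, Mt2, Hspa1a, Per2, Cry2, Nr1d2, H2-D1, B2m, Malat1, Fth1, Cst3 and the genes of microglia-like nuclei) were picked after their values had been seen.

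Alternatives planned in advance were TMM scaling (edgeR 4.0.16 in R 4.3.3), no UMI minimum for list members, 1000 genes per nucleus, doublet calls kept, nuclei chosen by at least 2 UMIs of Gad1 and Gad2 without clustering, an equal class mix, the mean over nuclei of each nucleus's CPM, male or female nuclei alone, genes centred within each library before clustering, Leiden resolution 0.5, and thinning to 1000 UMIs. Added after the data had been seen were the sum without clusters 23 and 31, scaling without Malat1 and mitochondrial genes, and an equal weight of the mice of each pool.

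The steps were tested on simulated counts drawn from the means and depths of these libraries for 18090 genes of the IL-13 over saline comparison. The 95% intervals held the true log2 ratio for 98%, 90%, 92% and 92% of 50 genes each set to -1, -0.5, 0.5 and 1, and for 95.4% of 15096 unchanged genes. Of 200 simulated lists of 30 genes, drawn from the 17890 unchanged genes with a finite ratio, 95% of those left unshifted fell between percentiles 2.5 and 97.5, and 100% of those shifted by 0.2 lay above. This test was written after the list values had first been computed. It held counting error only, with no variation between mice and none shared by genes of a list. The result for unshifted lists was thus close to fixed in advance. Mx1 and Mx2 of the interferon list are not among the symbols of the matrices.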

Results

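Nuclei of cortical inhibitory neurons were profiled to compare IL-13 with saline, in a series on group 2 innate lymphoid cells, inhibitory synapses and social behaviour. IL-13 is a type 2 cytokine made by such lymphoid cells and signals through Il4ra, Il13ra1 and Stat6. The dose was 200 ng, given into the ventricle at postnatal day 15, and tissue was taken 4 hours later. There was 1 library per group, each a pool of 1 male and 1 female mouse. The saline library held 8744 barcodes with 64644121 UMIs (median 6837 UMIs and 2760 genes per nucleus), and the IL-13 library 7926 barcodes with 59500333 UMIs (median 7143 UMIs and 2868 genes). GABAergic clusters held 8196 saline and 7322 IL-13 nuclei, with 59534957 and 55365135 UMIs. Of these, 4230 saline and 3116 IL-13 nuclei carried transcripts of the male mouse, 3046 and 3388 those of the female mouse, and 920 and 818 were not assigned. Each value below compares these libraries, without replicate error, and all intervals are 95% intervals of counting error.

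The first question was which interneuron classes were captured and whether they took like shares in both libraries. Pvalb-like nuclei, the fast-spiking class, made up 27.0% (interval 26.0 to 28.0) of saline and 26.4% (25.4 to 27.5) of IL-13 GABAergic nuclei. Sst-like nuclei, the dendrite-targeting class, took 23.96% (23.04 to 24.90) and 22.3% (21.4 to 23.3). Lamp5-like nuclei took 17.9% (17.1 to 18.7) and 19.9% (19.0 to 20.8), and Vip-like nuclei 14.0% (13.3 to 14.8) and 14.6% (13.8 to 15.5). Sncg-like nuclei made up 1.48% and 1.24%, and Chandelier-like nuclei 0.915% and 0.751%. Another 14.8% and 14.7% lay in 5 GABAergic clusters with no class name, the most numerous being cluster 0 with 722 and 691 nuclei, led by Il1rapl2, Ntng1 and Tll1. Cluster 0 had 7 Pvalb markers raised (mean log2 score 0.92). It missed that name only because Etv1, a Meis2 marker, was among its 10 leading genes. The Pvalb-like shares therefore leave out its 8.81% of saline and 9.44% of IL-13 GABAergic nuclei. Cluster 31, led by Meis2 and Foxp2 and with the striatal markers Rgs9 and Drd2 among its 10 leading genes, held 54 saline and 11 IL-13 nuclei, and nuclei of nearby striatum were not excluded. Within the Sst-like class, cluster 4 (led by Prkg2 and Pcsk5) held 644 and 365 nuclei, and cluster 23 (led by Gpc5 and Adamts18) held 5 and 161, of which 146 came from the IL-13 female mouse. At resolution 0.5, a Sst-like cluster led by Gpc5 and Adamts18 held 814 and 615 nuclei, with Pcsk5 and Prkg2 also among its leading genes. Whether clusters 4 and 23 are separate types was not tested. The GFP sort and the dissection can set the class shares, and with doublet calls kept the Pvalb-like shares were 21.3% and 22.1%.

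**Figure D1:**
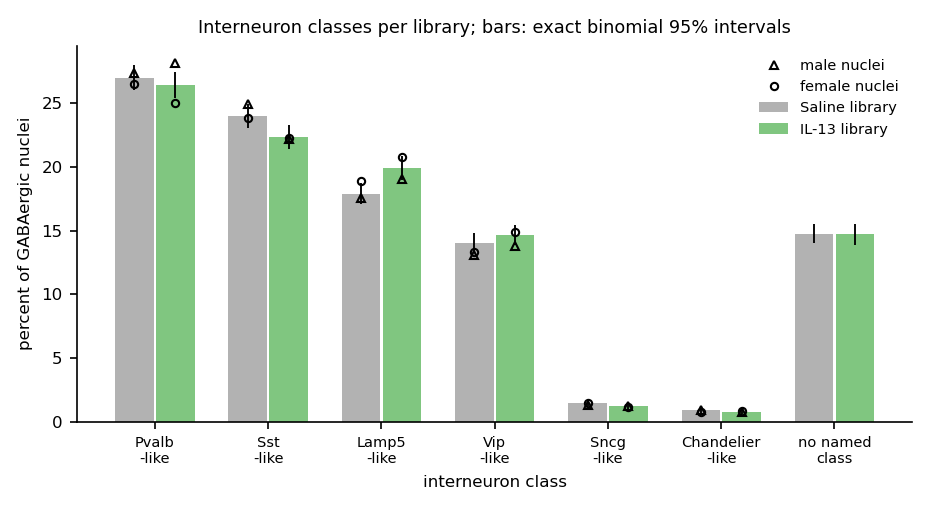
Share of GABAergic nuclei (percent, from 0) in each interneuron class for the saline (grey) and IL-13 (green) library, with exact binomial 95% intervals, and with triangles and circles for the nuclei of the male and female mouse in named classes. The Lamp5-like share was 17.9% in the saline and 19.9% in the IL-13 library.

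Transcripts of the IL-13 receptor were sparse in interneurons and unevenly spread over classes. Il4ra, the signalling chain shared by the IL-4 and IL-13 receptors, reached 6.89 CPM (5.01 to 9.25) in saline and 4.98 CPM (3.38 to 7.07) in IL-13 Vip-like nuclei. In Sst-like nuclei it was at 2.10 CPM (1.43 to 2.98) and 1.46 CPM (0.878 to 2.28), and in Pvalb-like nuclei at 0.229 CPM (0.0625 to 0.588) and 0.188 CPM (0.0388 to 0.550). Il13ra1, the other chain of the IL-13 receptor, was at 5.89 CPM (4.72 to 7.26) and 5.84 CPM (4.60 to 7.30) in Sst-like nuclei, 3.21 and 2.20 CPM in Pvalb-like, 2.82 and 3.69 CPM in Vip-like, and 1.97 and 1.61 CPM in Lamp5-like nuclei. Stat6, the transcription factor of this pathway, was highest in Sst-like nuclei at 1.42 CPM (0.880 to 2.17) and 2.61 CPM (1.81 to 3.65), and had no UMI in 1151 and 1071 Vip-like nuclei. After thinning to 2000 UMIs, Il4ra was seen in 1.57% of saline and 0.843% of IL-13 Vip-like nuclei (3.56% and 2.89% unthinned), against 0% of 2208 and 1931 Pvalb-like nuclei (0.181% and 0.155% unthinned, from 4 and 3 UMIs). Median depths were 5214 and 5574 UMIs for Vip-like and 7438 and 7782 for Pvalb-like nuclei, and thinning left out 6 and 3 Vip-like and 3 and 5 Pvalb-like nuclei. Oligodendrocyte-like nuclei, a separate cell type with median depths of 4006 and 4165 UMIs, showed no Il4ra or Il13ra1 UMI in 53 and 35 nuclei, but with upper limits of 14.9 and 24.7 CPM, above all interneuron values, this gives no background level. Microglia-like nuclei had more Il4ra, with 56.7 CPM (27.2 to 104.2) and 76.5 CPM (41.8 to 128.4) from 10 and 14 UMIs. Their Il13ra1 was at 17.0 CPM (3.51 to 49.7) and 27.3 CPM (8.87 to 63.8) from 3 and 5 UMIs, and the saline interval held the Sst-like value. Il13ra2, the decoy receptor, had 4 and 3 UMIs over all GABAergic nuclei, and Il2rg, the common cytokine receptor chain, had 0 and 1.

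Over all GABAergic nuclei Il4ra was lower in the IL-13 library (1.63 and 1.14 CPM, log2 ratio -0.52, interval -0.999 to -0.046). Il13ra1 (-0.22, -0.52 to 0.09) and Stat6 (0.54, -0.04 to 1.13) had intervals that included 0. The list of receptor and JAK-STAT6 components had a median of 0.08 (-0.04 to 0.11) over 10 measured members of 13, at percentile 79.4 of matched lists, and its sign was not the same under all alternatives. Among its members, the kinases Jak2 (-0.14) and Jak1 (-0.10) were lower, and Irs2 (0.20), an adaptor of insulin and IL-4 receptors, and the kinase Tyk2 (0.16) were higher.

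The next comparison was whether genes known to respond to IL-4 and IL-13 differed in interneurons at 4 hours. As a group they did not stand apart in these nuclei: the median log2 ratio was -0.01 (-0.07 to 0.07) over 20 measured of 37 genes, at percentile 20.2 of matched lists, with 8 members above and 12 below 0, and scaling without Malat1 and mitochondrial genes, a like shift of all genes, put it above 0. The pathway inhibitors Socs1 (2.20 and 2.15 CPM, ratio -0.03, -0.40 to 0.34) and Cish (-0.08, -0.76 to 0.59) were close to equal, and Socs3 had 3 and 8 UMIs. The nuclear receptor Pparg was higher (0.19, 0.13 to 0.25), with 0.52 in female and -0.14 in male nuclei, and the survival factor Mcl1 was at 0.10 (-0.04 to 0.23). Bcl6, a transcriptional repressor, was at -0.12 (-0.20 to -0.04), and Bcl2l1 at -0.03 (-0.12 to 0.06). Named classes gave medians from -0.02 in Vip-like to 0.06 in Sst-like nuclei. The median was -0.10 in male and 0.07 in female nuclei, so it had opposite signs in the mice, and 17 members were too sparse to be measured.

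Of 8291 genes past the CPM and UMI minimum of the ranking, 4948 had the same sign in both mice and were ranked. Among these, the highest ratios in the IL-13 library came mostly from its female mouse, and Apoe, Per1 and several lower genes had like values in both mice. Itgav (ENSMUSG00000027087, chromosome 2, 83724397 to 83806916 on GRCm38), an integrin alpha chain, went from 9.74 to 19.9 CPM (fold 2.05, log2 ratio 1.03, 0.89 to 1.18), with 0.02 in male and 1.68 in female nuclei. Ociad2 (0.75), Baiap2 (0.72, an actin regulator of dendritic spines), Peli2 (0.68, a ubiquitin ligase of innate immune receptors) and Krt12 (0.66, a keratin) followed. Necab3 was at 0.65 and the phosphatase Ptpn3 at 0.60. Pde6a (0.55) and Sag (0.54), both known from the phototransduction of rods, the secreted protease Htra1 (0.53) and Ankrd33b (0.53) completed the 12. Apoe, the lipid carrier made mostly by glia (chromosome 7, 19696109 to 19699188), was at 0.59 (0.43 to 0.74), with 0.66 in male and 0.43 in female nuclei. In the male nuclei 7 of these 12 (Itgav, Ociad2, Necab3, Ptpn3, Pde6a, Htra1 and Ankrd33b) lay below 0.10.

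Among lower genes, the homeobox factor Meis2 had the lowest ratio (chromosome 2, 115863064 to 116065839), with 16.8 and 6.34 CPM and a log2 ratio of -1.41 (-1.59 to -1.23). That value rested on the class mix: it was 0.25 with an equal class mix and 0.75 without clusters 23 and 31. The clock gene Per1 (chromosome 11, 69095217 to 69109960) was at -0.62 (-0.77 to -0.47), with -0.64 in male and -0.59 in female nuclei. Grm3, a metabotropic glutamate receptor, was at -0.46 (-0.51 to -0.41), with -0.32 and -0.59, and the collagen gene Col14a1 at -0.49, with -0.49 and -0.68. The kinase gene Camk1g (-0.48), Pkd2l2 (-0.47), Leng9 (-0.50) and the adhesion gene Nectin2 (-0.48) were also lower in both mice with intervals below 0. Moxd1 (-0.70), the cGMP-dependent kinase Prkg2 (-0.61) and the kinase Rps6ka5 (-0.46) were lower mainly in female nuclei, where they stood at -1.51, -1.19 and -0.89. Moxd1 and Prkg2 are among the 10 leading genes of cluster 4, which held 290 saline and 122 IL-13 female nuclei. Nell1os (-0.74) lies opposite to Nell1, and the use of strand in the counting was not given. Of the 24 genes, 23 kept their sign under all 11 alternatives, Meis2 being the exception. For male nuclei alone, female nuclei alone and an equal weight of the mice this was fixed by the choice of genes.

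**Figure D2:**
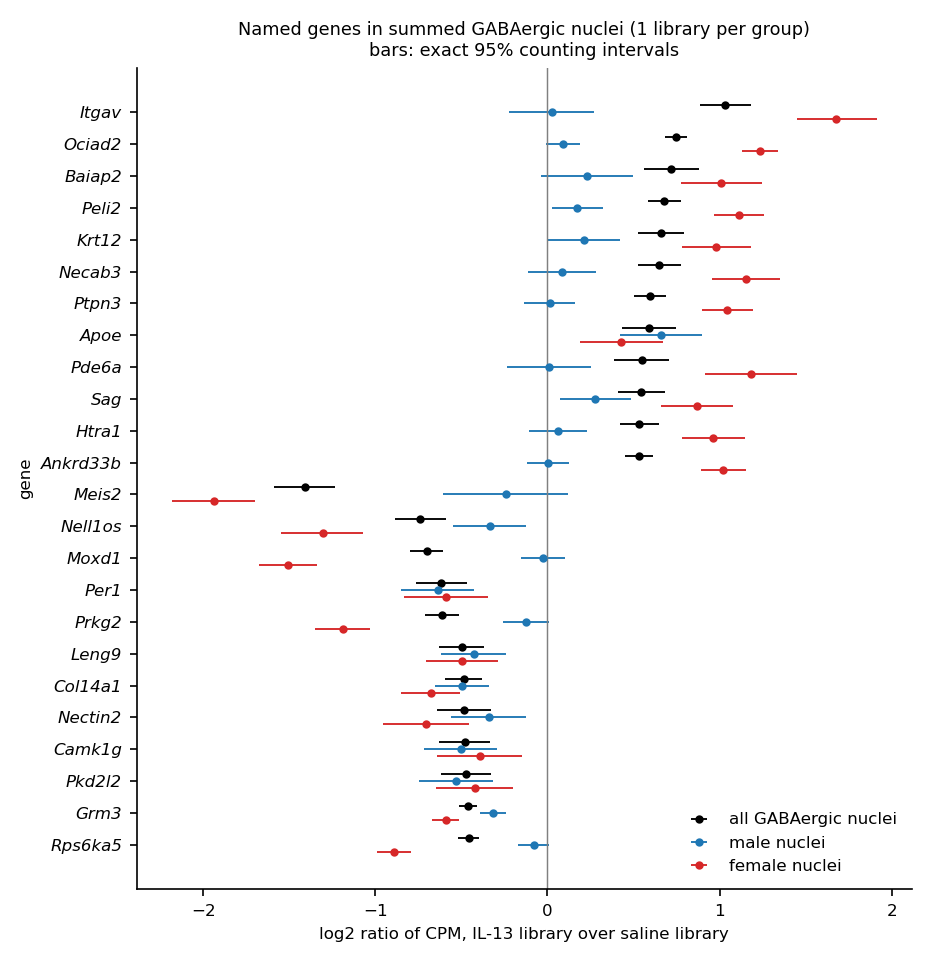
Log2 ratio of CPM (IL-13 over saline library) for the 24 named genes in all GABAergic nuclei (black), male nuclei (blue) and female nuclei (red), with exact 95% counting intervals. Itgav stands at 1.68 in female and 0.02 in male nuclei, and Per1 at -0.59 and -0.64.

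Immediate early and activity-dependent genes, which neurons induce upon firing, were higher in the IL-13 library as a group, and this came from the female mouse. The median was 0.15 (0.03 to 0.23) over 34 measured genes, at percentile 99.6, with 22 above and 12 below 0. It was 0.39 (percentile 100) in female and -0.05 (percentile 14.3) in male nuclei, and 12 members were above 0 in both mice. Scg2 (0.46, 0.38 to 0.53) and Vgf (0.43, 0.32 to 0.54), which encode secretory granule proteins, were highest among the more abundant members, and Homer1 (-0.16) and Nr4a1 (-0.13) lowest. The sparser Arc had 0.554 and 1.14 CPM (1.04, 0.41 to 1.69), Fos 2.74 and 3.45 CPM (0.33, 0.02 to 0.64) and Egr3 was at 0.69 (0.15 to 1.24). Nptx2, a pentraxin secreted at synapses, was at 1.22 (0.98 to 1.47) with 0.08 in male and 2.17 in female nuclei. By class the median was 0.27 in Sst-like nuclei (percentile 99.97), where clusters 4 and 23 differ between the libraries, and 0.00 in Pvalb-like, -0.05 in Lamp5-like and -0.05 in Vip-like nuclei.

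Genes of inhibitory synapses, the synapse type the series is about, had small medians over all nuclei, and those of the postsynapse were lower in female (-0.07) than in male nuclei (-0.01). The GABAergic postsynapse had a median of -0.03 (-0.05 to -0.01) over 30 genes, at percentile 9.81, with 22 below and 8 above 0. The receptor subunits Gabra2 (0.31, 0.26 to 0.36) and Gabrd (0.16, 0.10 to 0.22) were highest, and the receptor-associated Shisa7 (-0.22) and the adhesion molecule Nlgn2 (-0.21, -0.31 to -0.11) lowest. Gabrd was at 0.22 in male and 0.20 in female nuclei, and Nlgn2 at -0.17 and -0.23, while Gabra2 was at -0.04 and 0.55. GABA synthesis and presynaptic release had a median of -0.02 (-0.05 to -0.01) over 35 genes, at percentile 26.8. Gad2 (0.28, 0.25 to 0.30), which makes GABA, and the calcium channel Cacna1a (0.26) were highest, at 0.03 each in male and 0.47 each in female nuclei. Unc13c (-0.22), a factor of vesicle priming, was among the lowest, with -0.26 in male and -0.27 in female nuclei. Both medians were smaller in size than the shift between scalings, which is the same for all genes, and stood at 0.00030 and 0.0038 with scaling that left out Malat1 and mitochondrial genes.

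Genes of excitatory synapses and synaptic adhesion were lower as groups, with small medians. The glutamatergic postsynapse was at -0.07 (-0.09 to -0.05) over 44 genes, at percentile 0.090, with 33 below 0 and 22 below 0 in both mice. Grik3 (-0.30), a kainate receptor, was among the lowest, and Camk2b and Homer2 (0.18 each) highest. Synaptic adhesion molecules were at -0.08 (-0.10 to -0.06) over 43 genes, at percentile 0.060, led by Cntn6 (-0.37) and Tenm1 (-0.34), with Igsf9b (0.32) and Ntng1 (0.27) at the other end. That list was at -0.14 in female and -0.03 in male nuclei. Voltage-gated sodium and potassium channels were at 0.06 (0.02 to 0.07), at percentile 99.8, with Kcna1 (0.32) highest and Scn3b (-0.38) and Kcnh5 (-0.23) lowest, and the median had opposite signs in female (0.08) and male (-0.03) nuclei. Synaptic genes are long, and ratios followed gene length: the median ratio was 0.10 in the shortest and -0.02 in the longest of 5 equal bins of genes (median lengths 3735.5 and 135015 bases), with 0.08 and -0.04 in male and 0.12 and -0.0013 in female nuclei. Against lists matched on length as well, the glutamatergic and adhesion lists lay at percentiles 0.020 and 0.010, and the channel list at 99.5. Their median gene lengths were 165862, 363972 and 173072 bases, above the median of the longest bin. The match on 5 bins was thus coarse for them, and length was not excluded as a part of the lower glutamatergic and adhesion medians.

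**Figure D3:**
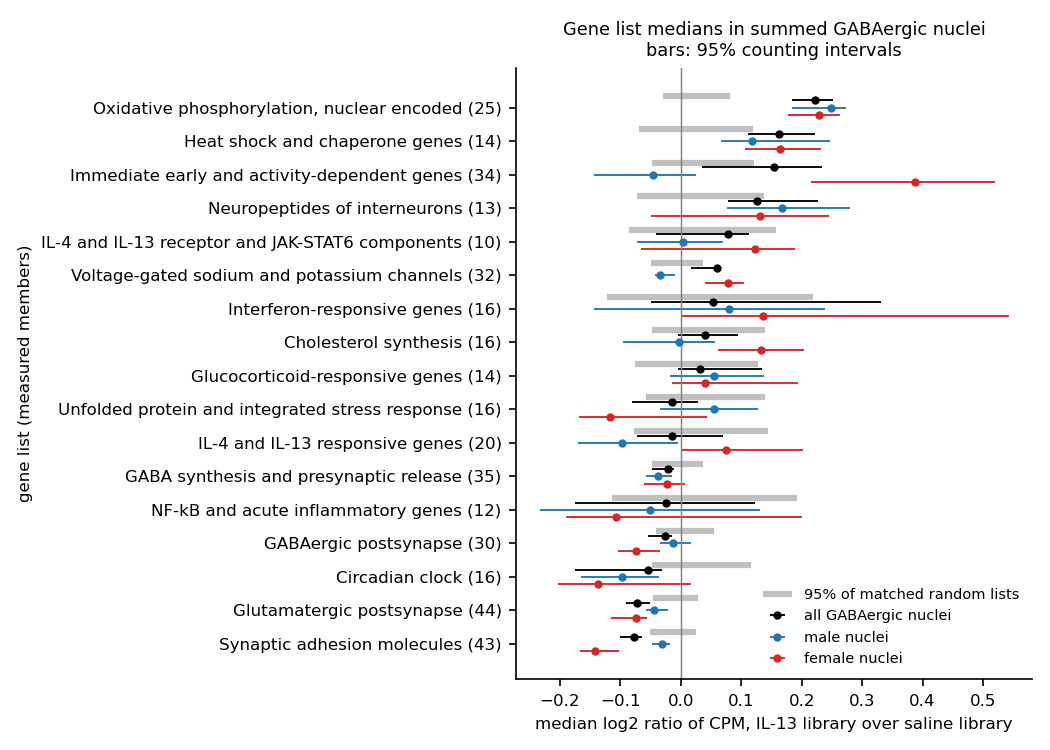
Median log2 ratio of CPM (IL-13 over saline library) of the 17 gene lists in all (black), male (blue) and female (red) nuclei, with 95% counting intervals, and grey bars for the range holding 95% of matched random lists. Nuclear-encoded oxidative phosphorylation genes stand at 0.22, and immediate early genes at 0.39 in female and -0.05 in male nuclei.

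Transcripts for mitochondrial respiration were higher in the IL-13 library in both mice. All 25 nuclear-encoded oxidative phosphorylation genes were above 0, with a median of 0.22 (0.18 to 0.25), at percentile 100, and 0.25 in male and 0.23 in female nuclei. Uqcrb (0.46) and Ndufb9 (0.39), subunits of complexes III and I, were highest, and Sdha (0.03) and Ndufs4 (0.08) lowest. The 13 mitochondrially encoded transcripts took 0.0996% of UMIs in the saline and 0.167% in the IL-13 library (0.75, 0.73 to 0.76), with 0.83 in male and 0.66 in female nuclei. Malat1, a nuclear long non-coding RNA with no part in respiration, was also higher, at 0.44. Heat shock and chaperone genes had a median of 0.16 (0.11 to 0.22), at percentile 99.6, with 12 of 14 above 0 and 10 above 0 in both mice. Hspa8 (0.25) and Hspe1 (0.23) were highest and Hsph1 (-0.09) and Hspa4l (-0.03) lowest among abundant members. Hspa1a, whose reads can be shared with its near-identical copy Hspa1b, was at 0.269 and 0.957 CPM (1.83, 1.00 to 2.74). These are mostly short genes, and matched on length the heat shock list lay at percentile 95.5 and the oxidative phosphorylation list at 100.

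Clock genes had a slightly lower median, inside the range holding 95% of random lists once length was matched, and 6 more lists given here lay inside it as well. The circadian list was at -0.05 (-0.18 to -0.03) over 16 genes, at percentile 1.71, or 3.86 when matched on length, with 12 below 0. Besides Per1, Hlf (-0.27), Per2 (-0.24), Nr1d2 (-0.22) and Cry2 (-0.20) were lower in both mice, and Npas2 and Clock (0.06 each) highest. The median was -0.23 in Lamp5-like, -0.19 in Sst-like, -0.07 in Pvalb-like and 0.05 in Vip-like nuclei. Glucocorticoid-responsive genes were at 0.03 (percentile 59.6), with Klf9 (0.30) and Errfi1 (0.12) highest and Per1 and Nr3c1 (-0.10), the glucocorticoid receptor, lowest among abundant members. The metallothioneins Mt1 (0.72, 0.55 to 0.90) and Mt2 (1.19, 0.78 to 1.62) were higher in both mice. Interferon-responsive genes were at 0.05 (percentile 52.6), with Xaf1 (1.51, 0.82 to 2.23) and the MHC class I gene H2-K1 (0.81, 0.24 to 1.39) highest and Rnf213 (-0.25) and Ifit1 (-0.21) lowest. H2-D1 (0.45) and B2m (0.51), partners in MHC class I, were above 0 in both mice, and H2-K1 and H2-D1 can share reads. NF-kB genes were at -0.02 (percentile 22.0), from Nfkb2 (-0.76) and Stat3 (-0.30) to Nfkbia (0.58) and Cebpb (0.35). Unfolded protein response genes were at -0.01 (percentile 13.9), from Xbp1 (-0.17) and Pdia6 (-0.13) to Atf4 (0.21) and Hspa5 (0.02), and cholesterol synthesis genes at 0.04 (percentile 46.2), from Msmo1 (-0.05) and Dhcr7 (-0.02) to Fdft1 (0.12) and Sc5d (0.11). Neuropeptide genes were at 0.13 (0.08 to 0.23, percentile 96.1, or 67.1 when matched on length), with Npy (0.41, 0.36 to 0.47) and Tac2 (0.30) highest and Cort (-0.24) and Crh (0.05) lowest among abundant members. The signs of the interferon, NF-kB, unfolded protein and cholesterol medians each turned under at least 1 alternative.

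Each class was then compared on its own, without a test of differences between classes, and many of the highest genes again came from the female mouse. In Lamp5-like nuclei Rgs20, a regulator of G protein signalling, was at 1.78 (1.41 to 2.17; 0.26 in male and 2.37 in female nuclei), Necab3 at 0.96 (0.06 and 1.54) and Clnk at 0.91 (0.60 and 1.12), and Arid5a (-1.04), the immediate early receptor Nr4a3 (-0.78) and Gcnt2 (-0.77) were lowest. In Pvalb-like nuclei the synaptic vesicle gene Sv2c was at 1.08 (0.75 to 1.43; 0.32 in male and 1.82 in female nuclei), Peli2 at 1.05 (0.42 and 1.57) and Tanc1 at 1.04 (0.24 and 1.89), and Cadps2 (-0.95), a factor of dense-core vesicle release, Rtl4 (-0.85) and Psd2 (-0.78) were lowest. Cadps2 was at -1.05 in male and -1.15 in female Pvalb-like nuclei. In Sst-like nuclei, of which clusters 4 and 23 were unevenly filled, Itgav was at 1.53 (1.24 to 1.82; 0.14 in male and 2.17 in female nuclei), Nptx2 at 1.25 (0.10 and 2.24) and Rab31 at 1.12 (0.28 and 1.96). Nell1os (-1.06; -0.33 and -1.93), Tmem132cos (-0.86; -0.63 and -0.95) and Moxd1 (-0.80; -0.12 and -1.59) were lowest. In Vip-like nuclei the kinase Ptk2b was at 0.96 (0.47 to 1.48; 0.60 in male and 1.42 in female nuclei), Fxyd4 at 0.96 (0.35 and 1.54) and the ribosomal Rpl35a, which has pseudogene copies, at 0.95 (0.47 and 1.28). The transcription factor Etv5 was lowest there at -0.99 (-1.23 to -0.75), with -1.07 in male and -0.77 in female nuclei, followed by Itgb8 (-0.91) and Brca2 (-0.87). In cluster 0 Thsd4 (2.30, 1.61 to 3.05), Peli2 (1.95) and Sytl5 (1.52) were highest, with 0.47, 0.03 and 0.20 in male and 2.98, 3.1 and 1.82 in female nuclei, and Rhou (-0.98), Slc35b4 (-0.98) and Scn3b (-0.93) lowest.

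Markers of interneuron classes and of other cell types were measured in the same sums. Sst class markers were lower (median -0.24, -0.29 to -0.16), led by Lypd6 (-0.40) and Grin3a (-0.37), while Sst itself was at 0.12. Markers of interneurons from the medial ganglionic eminence were at -0.11 and those from the caudal eminence at 0.04. Pvalb markers were at 0.05, Chandelier at 0.03, Vip at 0.13, Lamp5 at 0.11, Sncg at 0.06, Meis2 at -0.01 and pan-GABAergic markers at 0.08, with Pvalb itself at 0.37. Striatal projection neuron markers were at -0.19 and excitatory neuron markers at 0.12. Astrocyte markers were at 0.26 (0.04 to 0.39, percentile 98.3), with 0.03 in male and 0.41 in female nuclei, and microglia and macrophage markers at 0.21 (-0.02 to 0.51). P2ry12, the most abundant of the latter, was lower (-0.41, -0.52 to -0.29). The other measured ones were above 0, with C1qa highest at 1.10 (0.55 to 1.68, from 41 and 82 UMIs), and the intervals of the rest included 0. Oligodendrocyte markers were at 0.12, with 0.54 in male and -0.06 in female nuclei, precursor markers at 0.01, and red blood cell markers at 0.50 (-0.19 to 1.04). Endothelial (0.15), mural (-0.12), fibroblast (-0.01), ependymal and choroid plexus (0.0049) and lymphocyte and granulocyte (0.32) markers rested on at most 3 measured genes each. The same held for the oligodendrocyte precursor markers.

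The mice of each pool were set side by side over 8730 autosomal genes. The SD of log2 ratios between the male and female mouse was 0.124 within the saline pool and 0.189 within the IL-13 pool. Between libraries it was 0.130 for the male and 0.226 for the female mice. Across genes, which are not independent replicates, the male and female ratios had a Pearson correlation of 0.226 and a Spearman correlation of 0.263, and 59.9% of genes had the same sign.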

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

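The comparison of microglia-like nuclei, picked from 3 clusters outside the GABAergic ones, the list of border macrophage genes and the tests of this part were chosen after the values had been seen.

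Microglia-like nuclei, few in a sort for GFP of GABAergic neurons, stood out among nuclei outside the comparison of GABAergic neurons. Their IL-4 and IL-13 responsive genes went from 578 CPM (102 UMIs, 67 nuclei) in the saline to 1404 CPM (257 UMIs, 80 nuclei) in the IL-13 library, a pooled log2 ratio of 1.28 (0.94 to 1.63). The cytokine signalling inhibitor Socs2 had 5 and 43 UMIs, the mannose receptor Mrc1 13 and 53, the matrix protein gene Postn 1 and 19, the arginase Arg1 1 and 13, the kinase Pim1 1 and 12, and Socs1 0 and 8. Some other members were near equal or lower, such as Mcl1 (9 and 9), Tfrc (12 and 14) and Ppargc1b (15 and 9), and Chil3 and Retnla had none. Microglial genes (0.06, -0.15 to 0.27) and immediate early genes (0.06, -0.33 to 0.45) were close to equal in the same nuclei, and mitochondrial transcripts were higher (1.04, 0.81 to 1.28). Gad1 and Gad2 together stood at 442 and 361 CPM there, against 722 and 842 CPM in GABAergic nuclei, so neuronal RNA was part of these nuclei, and debris or doublets among them were not excluded. The responsive list was also higher in oligodendrocyte-like nuclei of the IL-13 library (71 and 62 UMIs, 0.53, 0.015 to 1.04).

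A list of 10 border macrophage genes was lower in the microglia-like nuclei of the IL-13 library (pooled log2 ratio -2.45, -3.53 to -1.51), with F13a1 at 18 and 0 UMIs and Stab1 at 35 and 8. By these genes there were not more border macrophages. The list left out the macrophage marker Mrc1, which is among the responsive genes that were higher, so this result rests on the choice of genes. In nuclei called male (32 of 67 saline and 15 of 80 IL-13), the responsive list was at 1.16 (0.55 to 1.76), although Ppargc1b (12 and 0 UMIs) and Pparg (6 and 0) were lower in them. Only 1 saline nucleus and 25 IL-13 nuclei were called female, and the rest were not assigned. At such low depth 1 stray Y-linked UMI can make a male call, so another mix of the mice was not excluded. Free RNA was assumed to raise the low-UMI nuclei of cluster 24 alike, and those of the IL-13 library held the list at 438 CPM (336 to 560). Their log2 ratio over saline was 0.26 (-0.57 to 1.18), from 15 and 63 UMIs. That interval overlapped the 0.94 to 1.63 of the microglia-like nuclei, so free RNA was not excluded. RNA added from neurons did not account for the level in the IL-13 library, since its GABAergic nuclei held the list at 430 CPM (424 to 435). A smaller share of neuronal RNA in the IL-13 than in the saline microglia-like nuclei would raise microglial genes as well. These stood at 0.06 (-0.15 to 0.27), against 1.28 for the responsive list. Synaptic lists were lower in the microglia-like nuclei of the IL-13 library, so such a share was not excluded as a part of the difference. In the male microglia-like nuclei, Gad1 and Gad2 were at 578 and 310 CPM (-0.90, -1.97 to 0.04), and microglial genes at 0.39 (-0.04 to 0.81). The state of a mouse and a difference in preparation were not tested, so the cause stays open, with 1 library per group and median depths of 1435 and 1516.5 UMIs.

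By list medians in the microglia-like nuclei, IL-4 and IL-13 responsive genes stood at 0.69 (percentile 98.1), with 10 of 12 measured genes above and 2 below 0. Heat shock genes (median 0.77, percentile 98.8) were also high, and GABAergic postsynapse (-0.79), channel (-0.68) and clock genes (-0.74) low in these nuclei. The glutamatergic postsynapse (-0.39, percentile 0.635) and GABA synthesis and release (-0.29, percentile 2.43) lay below the range of random lists as well. Neuronal RNA was part of these nuclei, so for synaptic and channel lists less of it in the IL-13 library was not separated from a change within microglia-like nuclei.

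The ratios of IL-13 over saline were wider in female than in male nuclei, and an equal class mix did not remove this, with SDs of 0.225 and 0.129. That mix left clusters within a class uneven, such as clusters 4 (290 saline and 122 IL-13 female nuclei) and 23 (0 and 146) of the Sst-like class. A different mix within classes was not tested. Counting error did not explain the wider female ratios, as the SDs were 0.212 and 0.107 after its variance had been subtracted. The female and male mouse of the IL-13 pool differed by an SD of 0.189, against 0.124 in the saline pool. A response of one sex and a state of one mouse cannot be told apart with 1 mouse per sex and group.

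Differences between the mice were not tested, and among the response lists and their named members the following had opposite signs with intervals on either side of 0. The median of IL-4 and IL-13 responsive genes was 0.074 in female and -0.097 in male nuclei. Sodium and potassium channels stood at 0.078 and -0.034. Pparg was at 0.52 and -0.14. The chaperone gene Hspa4l was at -0.14 and 0.11. Some class markers did so as well, among them Gad1 (0.29 and -0.06), Crhbp (0.46 and -0.24), Ndnf (-0.28 and 0.45) and Etv1 (-0.66 and 0.31). Cluster 24, made of nuclei with few UMIs and led by Gm42418, Atp6v0c and Taco1, held 1.44% of IL-13 (109) and 0.479% of saline nuclei (40), and was left out of the comparisons of GABAergic nuclei.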

How the results depend on the processing

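Of 204 list medians under the alternatives, 177 stayed within the counting interval, as did 905 of 1045 gene ratios, 67 of 84 class shares and 81 of 100 receptor shares. Oxidative phosphorylation (0.20 to 0.25), heat shock (0.12 to 0.19), adhesion (-0.14 to -0.03), glutamatergic (-0.10 to -0.04) and clock genes (-0.14 to -0.03) kept their sign throughout. Signs turned beyond counting error for the channels (-0.034), Pparg (-0.14) and Npas2 (-0.065) in male nuclei, and Meis2 with an equal class mix (0.25) and without clusters 23 and 31 (0.75), where the class mix is the cause by construction. Medians of another 9 lists changed sign as well, but their main interval held 0 or the new value lay within counting error of 0. Among them immediate early genes went from 0.15 to -0.045 in male nuclei, and IL-4 and IL-13 responsive genes from -0.01 to 0.074 in female nuclei. Of 26 medians that moved, 15 were of lists on IL-13, activity, GABA and glutamate. Among these, female nuclei gave receptor and JAK-STAT6 components 0.12, IL-4 and IL-13 responsive genes 0.074, immediate early genes 0.39 and GABAergic postsynapse -0.074. In male nuclei the last 3 were at -0.097, -0.045 and -0.012, and the glutamatergic postsynapse at -0.044. GABAergic postsynapse was at -0.014 without clusters 23 and 31. TMM, which subtracts 0.027 throughout, gave GABA synthesis and release -0.049 and the glutamatergic postsynapse -0.099. The mean over nuclei gave GABA synthesis and release -0.0060. Scaling without Malat1 and mitochondrial genes gave 0.00030 for the GABAergic postsynapse, 0.0038 for GABA synthesis and release and -0.046 for the glutamatergic postsynapse. Apart from scaling and Meis2, the cause was not tested. Depth limited receptor genes and 17 IL-4 and IL-13 responsive genes below 30 UMIs.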

Other observations

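Fth1 and Cst3 were picked, and the tests of this part were chosen, after the values had been seen. Fth1, the heavy chain of the iron store ferritin, was higher in the IL-13 library (0.49, 0.42 to 0.57), with 0.51 in male and 0.51 in female GABAergic nuclei. Cst3, which encodes the protease inhibitor cystatin C (chromosome 2, 148871722 to 148875692), was at 0.48 (0.40 to 0.56), with 0.50 and 0.46. All 13 mitochondrially encoded transcripts were higher in both mice, among them mt-Nd1 (0.86) and mt-Co1 (0.63).

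Mitochondrial and oxidative phosphorylation transcripts were higher in both mice, and mitochondrial transcripts were higher in oligodendrocyte-like nuclei as well (0.92, 0.71 to 1.14), so the difference was not limited to GABAergic nuclei. In the low-UMI nuclei of cluster 24 the ratio was 0.09 (-0.14 to 0.32), while oxidative phosphorylation genes, pooled, were higher there (0.36, 0.10 to 0.63) and in oligodendrocyte-like nuclei (0.41). Whether cytoplasmic or free RNA caused these differences stays open. Gene length did not account for the oxidative phosphorylation list, which at 0.22 lay at percentile 99.98 of a separate draw of lists matched on length and expression (95% of them between 0.04 and 0.16). Another class mix did not account for it either, since the median was 0.22 with an equal class mix. A technical origin in the preparation of 1 library was not excluded, and no response of the neurons to IL-13 is claimed.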
